A study of Homo sapiens with 20 samples.

How the data were processed

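Expression was measured on 20 single-colour arrays in monocytes and polymorphonuclear cells (PMN) of human umbilical cord blood, both isolated from 5 subjects and cultured with PBS or with lipopolysaccharide (LPS, endotoxin) for 4 h. Per the labels' protocols, total RNA was isolated on Qiagen RNeasy columns and amplified and biotin-labelled with the Ambion MessageAmp II kit. The array type is not given in the sources used here; the identifiers are of the Affymetrix kind, with control probe sets that carry the prefix AFFX. The deposited values were made with GCRMA (version entry 1.1), per the submitters' processing notes; its settings are not given in the sources used here. GCRMA is a method for Affymetrix arrays that corrects background by probe sequence, normalizes between arrays and summarises probes. The authors' values were taken as log2 signal, since they ran from 0.272 to 16.3 on all arrays; the log base itself is not given in the sources used here. The table held 54675 probe sets, 62 of them controls, with no missing value. Such values say little about changes near background, and a normalization between arrays can hide or create a shift shared by most probe sets.

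Groups followed the titles, source names and treatment entries of the labels, which were unanimous. The free-text description of every PBS library instead named dexamethasone for 1 h before LPS, and that of every LPS library PBS vehicle for 1 h before LPS. The conflict over the PBS libraries could not be resolved here. If the descriptions held, each comparison of LPS with PBS would set vehicle before LPS against dexamethasone before LPS. Each group held 5 libraries with the numbers 1 to 5.

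Array medians over all probe sets lay between log2 3.59 and 3.84, and 43.5% to 46.8% of probe sets were at log2 4 or more. The number of arrays limits the precision. No batch, slide or scan date was used here.

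Probe sets other than controls were tested where at least 5 arrays reached log2 4, which kept 26338 and left out 28275. A group-means model of all 20 arrays was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that every comparison shared 1 estimate of the spread. p-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, and an adjusted p under 0.05 was a call. The comparisons were LPS against PBS in each cell type, the difference of these responses between the cell types (the interaction), monocytes against PMN under PBS and under LPS, and the overlap of the LPS calls. This design, the filter, the rule for named genes and the first set of alternatives were fixed before the data were examined.

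The files do not pair the probe set identifiers with genes, and the gene table supplied (assembly GRCh38.p14) could not be matched to them. Features are therefore probe sets, several of which can belong to 1 gene, and counts of probe sets are not counts of genes. The planned reduction to 1 probe set per gene, the tests of 42 gene lists with 804 genes (camera, fry) and the cell type markers were not run, and most of the genes planned for naming are not named. The rule for named genes took the probe sets with the largest rise and fall among calls in which the 5 LPS and 5 PBS values did not overlap. At most 2 identifiers that rose and 2 that fell are printed for each LPS comparison. Where a group mean of such a probe set lay under log2 4, the change is given as a lower bound with that mean set to log2 4. Counts at 2-fold or 4-fold and median changes use the values as deposited, also those under log2 4. In addition, 6 control probe sets of GAPDH and beta-actin were fitted along with the tested ones, with their p-values adjusted over both; they were chosen after the files were seen, because their identifiers name a transcript. They stand outside all counts of calls. A further 1 item is not reported here.

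The labels give the groups shared numbers, and the design text names 5 subjects. Whether the numbers pair the libraries was checked from the correlation of same-numbered libraries after subtracting group means. It was 0.419 to 0.721 between monocyte PBS and LPS, 0.519 to 0.705 between PMN PBS and LPS, 0.207 to 0.514 between the cell types under PBS and 0.328 to 0.388 under LPS. A library correlated best with its own number in 5, 5, 4 and 5 of 5 cases. Every pair lay above 0.1, so the numbers were taken to pair the libraries. The main fit, fixed before this check, does not use the pairs, so its p-values treat paired libraries as independent. A fit with the replicate block (within each cell type for LPS, over both for cell types) is given beside a result where it moved a count by over 1.5 times.

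The position of each library between PBS and LPS was computed from 200 probe sets with the strongest LPS change among the libraries of the other 4 numbers of its cell type. A value of 0 is the mean of the other PBS libraries and 1 the mean of the other LPS libraries. RNA quality was read from the difference of the 3' and 5' probe sets of beta-actin and GAPDH, which grows when RNA is degraded or copied incompletely.

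Alternatives were the block as a fixed or random effect, only the groups compared, quantile normalization on top, centring on array medians, no filter or a filter at log2 6, trend and robust eBayes, array weights, a 2-fold threshold and leaving out each library in turn. Chosen after seeing the data were centring each array on the median of its differences from the probe set means, leaving out monocyte PBS 4 with PMN PBS 5, leaving out both PMN libraries of number 1, and the block without the first pair. The calling steps were tested on simulated data for LPS against PBS in monocytes over 26338 probe sets. Of 100 probe sets shifted by 1 on the log2 scale 43 were recovered, of 100 shifted by 2 there were 88, and 9 unchanged ones were called. The simulated noise was independent between probe sets and arrays, without pairs or a library standing apart. These figures therefore need not hold for the real arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.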

Results

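The LPS response of newborn phagocytes was compared between monocytes and polymorphonuclear cells (PMN, mostly neutrophils), the main circulating cells that take up bacteria. Both were isolated from cord blood of 5 subjects and kept for 4 h with PBS or with 10 ng/mL of LPS, the endotoxin of Gram-negative bacteria. Each of the 4 groups held 5 libraries, 1 array each. The series title places the work in the control of cytokine genes by interleukin-10; cytokine genes are not named here, because the identifiers are not paired with genes, and results are given for probe sets and for control probe sets that name a transcript. The PBS groups follow the title and treatment entries, although their description mentions dexamethasone followed by LPS, and that of the LPS groups PBS vehicle followed by LPS. Statements on LPS below hold only if the title and treatment entries are right.

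Cell type set the libraries apart more than LPS did. The first principal component of the log2 values held 56.6% of the variance and parted all monocyte from all PMN libraries. The second held 14.6% and ordered PBS above LPS within each cell type, except for monocyte PBS 4, which lay among the monocyte LPS libraries. On the scale from PBS (0) to LPS (1), monocyte PBS 4 lay at 0.996 and PMN PBS 5 at 0.577, while the other PBS libraries lay between -0.286 and 0.0328. LPS libraries lay between 0.919 and 1.19 in monocytes and between 0.836 and 1.11 in PMN. Monocyte PBS 4 correlated best with monocyte LPS 4 (r = 0.992 across probe sets, which are not independent replicates), and PMN PBS 5 with PMN LPS 5 (r = 0.993). In both PMN libraries of number 1 the beta-actin 3' signal exceeded the 5' signal by 6.55 (PBS) and 6.16 (LPS) on the log2 scale, against 0.751 to 2.02 in the other libraries.

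**Figure D1:**
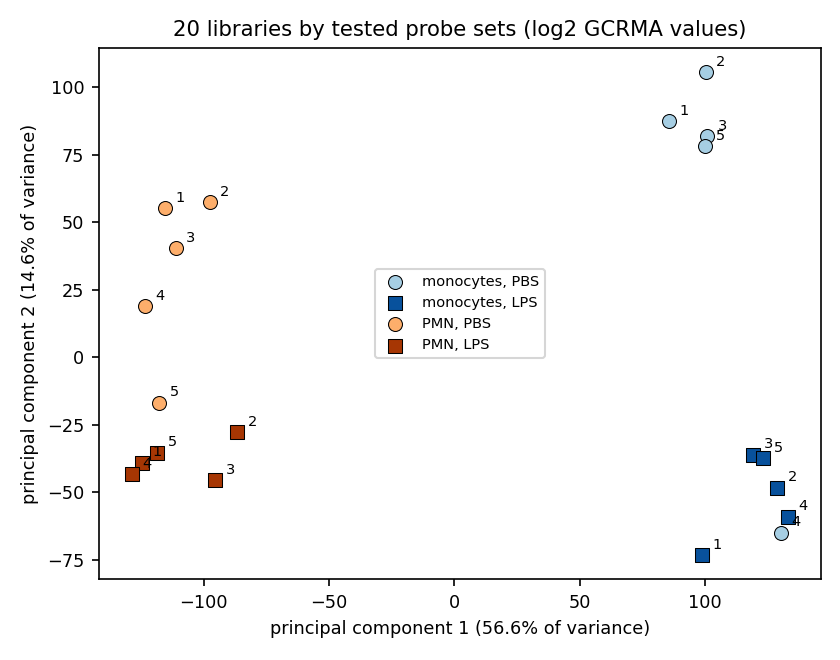
Scores of the 20 libraries on the first (horizontal) and second (vertical) principal components of the tested log2 values, numbered by replicate; circles are PBS and squares LPS, blue monocytes and orange PMN. Monocytes and PMN separate along the first component (56.6% of the variance), and monocyte PBS 4 lies among the monocyte LPS libraries.

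**Figure D2:**
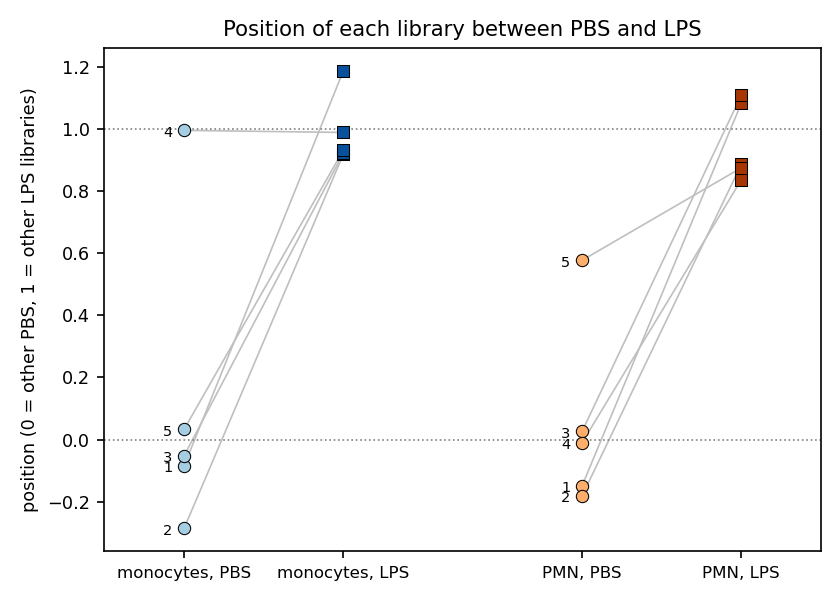
Position of each library between the other PBS (0) and the other LPS (1) libraries of its cell type (vertical, no unit); points are single libraries, lines join the same number. Monocyte PBS 4 lies at 0.996 and PMN PBS 5 at 0.577.

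Which transcripts LPS changed in monocytes was asked first. LPS moved 3077 of 26338 probe sets (11.7%), of which 980 rose and 2097 fell. Rises reached further on the values as deposited, those under log2 4 included. At least 4-fold, 385 probe sets rose and 266 fell. The median log2 change was 1.67 over all 980 risers and -1.13 over all 2097 fallers. The control transcripts GAPDH, a glycolytic enzyme, and beta-actin, a cytoskeletal protein, had 3' log2 differences of -0.29 (limma adjusted p = 0.303, 0.0548 to 0.663 over the alternatives) and -0.08 (adjusted p = 0.746, 0.578 to 0.994), the latter with 0.08 after centring on array medians. All 3 GAPDH probe sets were lower with LPS in 5 of 5 monocyte pairs, and their mean differences kept this direction after each scaling. The middle one, at -0.43 (limma adjusted p = 0.24), passed with the replicate block (adjusted p = 0.0209, and up to 0.449 over the alternatives).

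Among probe sets whose LPS and PBS values did not overlap, 227140_AT rose most with all libraries, by 5.66 on the log2 scale from log2 8.23 ± 2.58 to 13.89 ± 0.68 (SD, n = 5; limma adjusted p = 0.00263). This rule leaves out probe sets in which monocyte PBS 4 reached the LPS values, and 228 of the 980 risers met it. One left out was 205207_AT, with monocyte means of 8.19 with PBS and 13.90 with LPS but 14.21 in PBS 4. 214581_X_AT rose by 5.49 on the log2 scale (SE 0.80), from 5.51 ± 2.62 (SD, n = 5; limma adjusted p = 0.000809), while its PMN means were 3.54 with PBS and 3.56 with LPS, under the floor of log2 4. 202838_AT fell from 8.30 ± 2.30 to 3.46 ± 0.59 (SD, n = 5; limma adjusted p = 0.00147), also under the floor with LPS, so its fall was at least 4.30 on the log2 scale, down to the floor. 229635_AT fell from 8.77 ± 1.79 to 4.60 ± 0.41 (SD, n = 5; limma adjusted p = 0.000823). Without monocyte PBS 4 the log2 changes of 227140_AT, 214581_X_AT and 229635_AT were 6.56, 6.64 and -4.94 and the fall of 202838_AT at least 5.25, and without monocyte PBS 2 that of 227140_AT was 4.78. Of both risers, 214581_X_AT had the larger change without monocyte PBS 4, without PBS 2 (5.29) and with array weights (6.36 against 6.30). Groups did not overlap for 365 probe sets upward and 1414 downward, 6.75% of those tested against 0.794% by chance for unpaired libraries. The libraries were taken as paired and probe sets are not independent, so the excess is not a test. The share of falls among calls was 68.2% as deposited, 56.1% after quantile normalization, 66.6% after centring on the median difference from the probe set means, and 46.7% after centring on array medians, which moved the median log2 change of all tested probe sets from -0.03 to 0.13. The count was 6698 (2172 rose, 4526 fell) with the replicate block, 5756 (2169 rose, 3587 fell) without monocyte PBS 4 and PMN PBS 5, and 2048 with a change of at least 2-fold. Leaving out a single library gave 5620 without monocyte PBS 4, 1903 without PBS 1, 1735 without PBS 2, 1910 without PBS 5 and 1843 without monocyte LPS 1.

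The same question was put to PMN. LPS moved 2168 probe sets (8.23%), of which 589 rose and 1579 fell, and 143 rose and 117 fell at least 4-fold. GAPDH and beta-actin had 3' log2 differences of -0.22 and -0.16 (limma adjusted p = 0.501 and 0.457), lower with LPS in 4 and 5 of 5 pairs, and no alternative gave a call. The middle beta-actin probe set, at -0.09 (limma adjusted p = 0.942), was also lower in 5 of 5 pairs, with a mean difference of 0.02 after centring on array medians. The 5' one was lower in 4 of 5 pairs, although its mean log2 difference was 0.06 (limma adjusted p = 0.985).

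Among probe sets whose LPS and PBS values did not overlap in PMN, the largest rise with all libraries was that of 205207_AT, from log2 3.82 ± 0.45, under the floor, to 11.33 ± 1.52 (SD, n = 5; limma adjusted p = 0.00154), a rise of at least 7.33 from the floor. In monocytes this probe set had 8.19 ± 3.45 with PBS, or 6.68 ± 0.86 without monocyte PBS 4 (14.21), and 13.90 ± 0.63 with LPS. 238727_AT rose from 5.94 ± 1.65 to 10.82 ± 0.47 (SD, n = 5; limma adjusted p = 0.00363). 229889_AT fell from 7.69 ± 1.56 to 3.37 ± 0.85 (SD, n = 5; limma adjusted p = 0.000454), under the floor with LPS, a fall of at least 3.69 down to the floor, and was under it in monocytes with PBS (2.71) and LPS (2.36). 201506_AT fell from 8.68 ± 1.43 to 4.56 ± 1.06 (SD, n = 5; limma adjusted p = 0.00136). Without PMN PBS 5 the log2 change of 238727_AT was 5.54 instead of 4.88 and the fall of 229889_AT at least 4.32. Its place among the named falls rested on values under the floor and has no order against that of 201506_AT. Groups did not overlap for 673 probe sets upward and 1012 downward, 6.40% of those tested against 0.794% by chance for unpaired libraries. As in monocytes, this excess is not a test. Falls made up 72.8% of calls as deposited, 59.8% after quantile normalization, 69.9% after centring on median differences and 57.8% after centring on array medians, which moved the median change of all tested probe sets from -0.01 to 0.10. The count was 5552 (1686 rose, 3866 fell) with the replicate block, 4081 (1137 rose, 2944 fell) without monocyte PBS 4 and PMN PBS 5, 776 (196 rose, 580 fell) without both PMN libraries of number 1, 1081 with only the PMN groups in the model, and 1377 with a change of at least 2-fold. Leaving out a single library gave 1202 without PMN PBS 1, 1230 without PBS 2, 1327 without PBS 4 and 1251 without PMN LPS 3.

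Whether the response differed between the cell types was tested as an interaction. It differed for 162 probe sets (0.615%), with 98 more positive and 64 more negative in monocytes. Of the 98, 44 rose in monocytes with no call in PMN, 12 rose in monocytes and fell in PMN, and 42 fell in PMN with no call in monocytes. Of the 64, 31 fell in monocytes with no call in PMN, 25 rose in PMN with no call in monocytes, 7 fell in monocytes and rose in PMN, and 1 rose in both and more in PMN. The largest positive difference, that of 214581_X_AT, came with PMN means under the floor of log2 4 (3.54 with PBS and 3.56 with LPS). 229889_AT lay under it in monocytes (2.71 and 2.36). For such probe sets a lack of response cannot be told apart from a signal too low to measure. How many of the 162 were of this kind was not counted.

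The count of differing responses depended on the use of the pairs and on single libraries. With the replicate block, which uses the pairs, it was 1492 (830 and 662). Leaving out libraries gave a count of 1949 (1135 and 814) without monocyte PBS 4 and PMN PBS 5 and 1763 without monocyte PBS 4 alone. The count was 382 without PMN PBS 5 alone and 46 without both PMN libraries of number 1. It was 103, 97 and 106 without monocyte PBS 1, 3 or 5, 104 without PMN PBS 4, and 1584 with array weights. At an unadjusted p under 0.05 it was 3262, where chance alone gives about 1317.

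**Figure D3:**
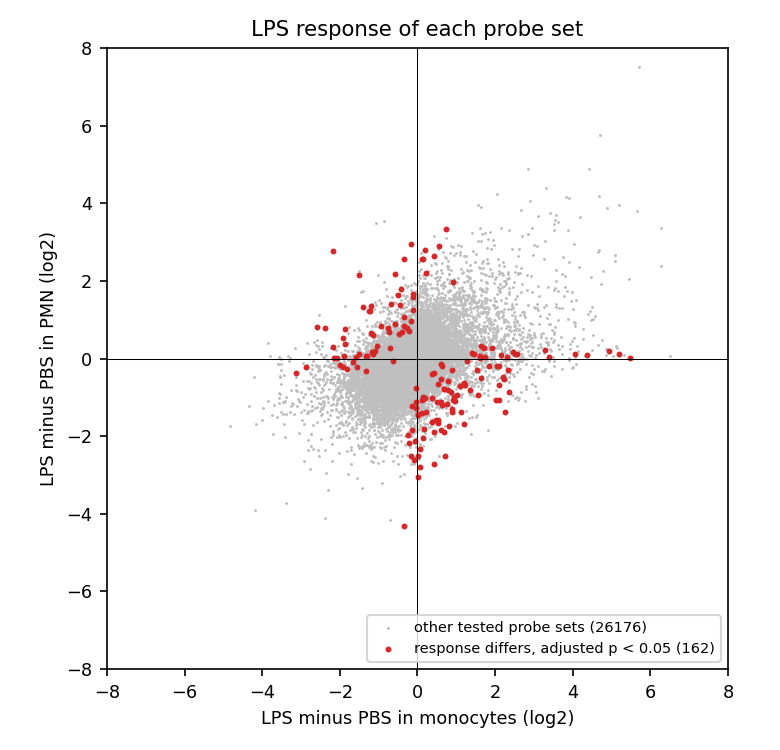
Log2 change with LPS of each tested probe set in monocytes (horizontal) and in PMN (vertical), from 5 libraries per group. Red points are the 162 probe sets whose response differed (limma), and the correlation across probe sets is 0.484.

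The responses of the cell types overlapped. The calls shared 128 probe sets that rose in both monocytes and PMN, against 21.9 for independent lists, and 420 that fell in both, against 126. These 548 stood beside 19 called in opposite directions. Falls made up 76.6% of the shared calls as deposited, 57.8% after quantile normalization, 73.7% after centring on median differences and 48.5% after centring on array medians. The cell types had separate PBS libraries, although from the same subjects. Both comparisons also used the same estimate of the spread of each probe set. The lists could therefore not be independent, and the excess, here and in the fits below, is not a test. The log2 changes correlated with r = 0.484 and rho = 0.481 across probe sets, which are not independent replicates. The overlap was 1846 (439 rose, 1407 fell) with the replicate block, with 139 and 664 for independent lists. It was 1755 (498 rose, 1257 fell) without monocyte PBS 4 and PMN PBS 5, with 93.6 and 401 for independent lists. Single libraries moved it to 334, 305, 1251 and 333 without monocyte PBS 1, 2, 4 or 5, to 336 without monocyte LPS 1, to 333, 297, 324 and 872 without PMN PBS 1, 2, 4 or 5, and to 306 without PMN LPS 3. The overlap was 223 without both PMN libraries of number 1, 263 with no filter and 300 with only the groups compared. With a 2-fold threshold it was 308, with array weights 1370 and with the block as a random effect 1234.

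Monocytes and PMN differed widely with or without LPS. Under PBS, 12804 probe sets (48.6%) differed, 7329 higher and 5475 lower in monocytes, with 2167 and 1402 of them at least 4-fold apart. Under LPS, 12555 (47.7%) differed, 7060 higher and 5495 lower, with 2289 and 1536 at least 4-fold apart. Monocytes were higher in both conditions for 5680 probe sets, against 1965 for independent lists, and lower in both for 3936, against 1142, while 22 were called on opposite sides. The PBS and LPS libraries of a cell type came from the same subjects, so the lists could not be independent and the excess is not a test. The share of calls lower in monocytes was 42.8% under PBS as deposited, 43.0% after centring on median differences, 51.2% after quantile normalization and 62.9% after centring on array medians. Under LPS it was 43.8%, 44.9%, 51.2% and 60.1%. Centring on array medians moved the median difference of all tested probe sets from -0.03 to -0.28 under PBS and from -0.04 to -0.24 under LPS, and quantile normalization moved it to -0.10 and -0.09.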

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

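The tests of the PBS libraries near LPS, the bound for the scaling test, the centring on median differences and the splits for the difference of responses were chosen only after the result was seen. Of 52 groups of 5 values searched for a library far from the others, 11 held one, where chance would give about 2.6 for independent groups. These groups were not independent: the same libraries recur in them, and the probe sets searched were picked for large LPS changes. The excess over 2.6 is therefore not a test.

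LPS moved transcripts differently in monocytes and PMN for 162 probe sets by the interaction test. In monocyte PBS 4, 214581_X_AT (10.13), 205207_AT (14.21) and 238727_AT (9.48) lay far above and 201506_AT (11.78) far below the other monocyte PBS libraries. In PMN PBS 5, 227140_AT (6.33) lay far above the other PMN PBS libraries. Monocyte LPS 1 had a position of 1.19, beyond the other LPS libraries. The beta-actin 3' minus 5' difference of PMN number 1 was 6.55 with PBS and 6.16 with LPS, and its GAPDH difference with LPS was 2.53.

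The first pattern is that of PBS libraries near LPS, monocyte PBS 4 at 0.996 and PMN PBS 5 at 0.577. An exchange with the LPS library of the same number is argued against by the positions of those, 0.989 and 0.875, and activation of both cell types of a subject before culture by the PBS library of the other cell type, at -0.0100 and 0.0328. Degraded RNA is argued against by beta-actin differences of 0.790 and 0.796, which were not raised. For monocyte PBS 4 a library wholly of LPS-exposed cells, from a wrong label or LPS in the culture, remains a candidate explanation, since 0.996 lies above 0.762, the mean of the monocyte LPS libraries less 2 SD; PMN PBS 5 at 0.577 lies below that bound for PMN, 0.703, which argues against a wholly exposed library and leaves a partial exposure or mixture open, untested. Activation of 1 cell type of a subject before culture is an untested biological explanation in both cases. The description of every PBS library, which names dexamethasone followed by LPS, remains unresolved, and its bearing on these positions was not tested.

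The second pattern is that more probe sets fell than rose in both cell types. Scaling between arrays cannot be told apart from a true excess of falls here. Centring on array medians brought the share of falls to 46.7% in monocytes and 57.8% in PMN, but it moved the median change of all tested probe sets away from 0, to 0.13 and 0.10, and that shift itself turns falls into rises. Quantile normalization left 56.1% and 59.8%, and centring on median differences, which moved the median change little, 66.6% and 69.9%. No biological explanation was tested.

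Chance was tested with 100 drawn splits of the same libraries for each comparison, the real one included. For PMN (2168 against at most 996) only 1 split, the real one, gave as many calls. The same held for monocytes against PMN under PBS (12804 against at most 4259) and under LPS (12555 against at most 2552). Most of the drawn splits leave pairs together, although the numbers were taken to pair the libraries, so these shares cannot exclude chance. In each of these comparisons the 16 possible splits that part all pairs are too few for a share under 0.05. Among those drawn, the real one included, the highest other gave 2 calls in PMN (13 such splits), 1207 between cell types under PBS (12 such splits) and 445 under LPS (11 such splits). For LPS in monocytes 3 of 100 splits gave as many as 3077, the highest 4177. This share cannot exclude chance either, since most of the splits again leave pairs together. The highest split put monocyte PBS 4 on the LPS side and monocyte LPS 5 on the PBS side, a structure of the samples. The splits that part all pairs are again 16 and too few for a share under 0.05; among the 13 drawn, the real one gave 3077 and the highest other, with PBS 4 and LPS 4 exchanged, 2864. For the difference of responses, the PBS and LPS libraries of a number moved together between the cell types after each was centred on its mean. Only 1 of 100 such splits, the real one, gave as many as 162, the highest other giving 0. Most of these splits leave both cell types of a number together, so this share cannot exclude chance. The 16 that part all pairs are too few for a share under 0.05, and the highest other of the 11 drawn gave 0. The count itself was 46 without both PMN libraries of number 1.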

How the results depend on the processing

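The 8 LPS calls of probe sets named by identifier kept their direction and stayed past the threshold under every alternative in which they were recomputed. 229889_AT was not tested with the filter at log2 6, and none was recomputed for the 2-fold threshold. These 8 were picked from the same data for large changes without overlap of the groups. Their stability was thus largely set by the choice and says nothing about other calls. Centring on median differences, leaving out libraries of number 1 in PMN, monocyte PBS 4 with PMN PBS 5, and the last with the block were chosen after seeing the data. The replicate block gave 6698 calls in monocytes, 5552 in PMN, 1492 for the difference of responses and 1846 for the overlap, and changed the counts between cell types by under 1.5 times (14752 and 14502). As a random effect (consensus correlation 0.265) it gave 5020, 3943, 703 and 1234. With only the groups compared, PMN had 1081 and the overlap 300; this setting gives no value for the difference, which needs all groups. No filter gave an overlap of 263, where more probe sets were tested. Array weights gave 6368 in monocytes, 1584 for the difference and 1370 for the overlap. A 2-fold threshold gave 2048, 1377 and an overlap of 308. Without monocyte PBS 4 and PMN PBS 5 the counts were 5756, 4081, 1949 and 1755, and with the block as well 9464, 7599, 4528 and 3724. Without both PMN libraries of number 1, PMN had 776, the difference 46 and the overlap 223. Leaving out single libraries gave 1735 to 5620 in monocytes, 1202 to 3250 in PMN, 97 to 1763 for the difference, 297 to 1251 for the overlap, 11725 to 12923 between cell types under PBS and 11305 to 12458 under LPS. Fewer libraries or other numbers of probe sets tested can change a count. The counts of 5620, 1763 and 1251 came without monocyte PBS 4, which lay near LPS and had the lowest array weight (0.241). Fewer libraries do not account for these rises. The cause of the changes in counts was not tested. The 3' change of beta-actin in monocytes, near 0 and never called, changed sign with centring on array medians (0.0838). That of its middle probe set in PMN did so with centring on array medians (0.0230), array weights (0.0210), without monocyte PBS 4 and PMN PBS 5 (0.0417) and without some single libraries (-0.47 to 0.34). Of 344 recomputed values of named probe sets, 335 kept direction and side of the threshold, 7 changed sign and 2 newly passed, both of the middle GAPDH probe set in monocytes. The alternatives with another probe set per gene and all those for gene lists were not run, because probe sets are not paired with genes. Probe sets near background, under log2 4, limit what can be measured.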

Other observations

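The values in this part were chosen after the data were seen. Pairs of the same number were compared for how far they followed the LPS response of the rest. The slope of each pair's changes against the mean changes of the other pairs was 1.27, 1.21, 0.974 and 0.899 for monocyte numbers 1, 2, 3 and 5, and 1.23, 1.07, 1.08 and 0.846 for PMN numbers 1, 2, 3 and 4. It was -0.00673 for monocyte number 4 and 0.298 for PMN number 5. For the other numbers of each cell type the mean changes included this weak pair, which can raise their slopes. The positions between PBS and LPS have the same limit.

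No probe set was under log2 4 in all PBS libraries and at log2 6 or more in all LPS libraries of a cell type. Without monocyte PBS 4, 17 did so in monocytes and 7 went the opposite way; without PMN PBS 5, 1 did so in PMN and 1 went the opposite way. Both counts are values without a test.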
